A study of Mus musculus with 34 samples.

How the data were processed

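Cells of mouse brain were dissociated from slices kept in oxygenated fluid, digested with pronase, filtered and freed of myelin debris, and captured with 10x Genomics 3' kits, per the labels' protocols. The deposited values are raw UMI counts per gene and cell barcode, made with Cell Ranger on the mm10 genome, per the file headers and the submitters' processing notes. The Cell Ranger version was 3.0.2 for cortex replicate 0 and hippocampus replicate 0, 6.0.0 for the other 2-month libraries, 4.0.0 for wild-type replicates 1 and 4 and transgenic replicates 1, 2 and 4, and 5.0.0 for the other frontal cortex libraries, per the file headers. The 3.0.2 libraries have 31053 genes and the others 32285, and the 30406 gene identifiers in both were used. The matrices hold called cells. Whether introns were counted, how overlapping or antisense genes were told apart, and the kit version of each library are not given in the sources used here. Counts of genes with near-identical copies, such as H2-D1 and H2-K1 or C4b and its paralogue C4a, depend on how shared reads were assigned upstream and carry that uncertainty.

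Groups were taken from the labels: cortex, hippocampus and striatum at 2 months, and wild-type and transgenic frontal cortex at 10 to 11 months. Old and young libraries were never compared, since age, dissection and colony differ together. Sex is not given in the sources used here, nor is whether each library came from its own animal, so replicates may in part be technical.

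A barcode was kept with at least 500 UMIs, 300 genes and at most 20% mitochondrial UMIs. Of 162111 barcodes 140461 were kept: 30313 of 36005 in cortex, 45444 of 50204 in hippocampus, 14755 of 17263 in striatum, 21613 of 25671 in wild-type and 28336 of 32968 in transgenic frontal cortex. Doublets were scored per library with Scrublet's method, and the highest-scoring cells, 0.8% per 1000 barcodes, were marked: 7034 cells, 5.008% of those kept (1.638% to 8.794% per library). They were left out of class sums and shares. Log-normalised counts of 2000 variable genes gave 40 principal components, a graph of 20 neighbours and 67 Leiden clusters at resolution 1.5 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0), with no batch integration.

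A cluster was named from its 10 top genes by fold over the 25th percentile of clusters, with 20 CPM added to both sides. It took a name with at least 3 markers of a type among them, at least 3 times those of any other type, and at most 40% doublet-marked cells. The markers were fixed before the data were examined, the thresholds of the naming after. This named 45 clusters in 17 classes and left 22 clusters with 13294 cells (9.465%) unnamed: 4.61% of cells in cortex, 11.85% in hippocampus, 9.01% in striatum, 3.49% in wild-type and 3.89% in transgenic frontal cortex.

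For gene tests, raw UMI counts were summed per library and class, with at least 50 cells of the class in a library. edgeR 4.0.16 (R 4.3.3) was the main test: filterByExpr, TMM scaling, and the two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The 15 young libraries entered a single fit per class with a mean per region, so striatum shares the spread of the other regions. The 19 frontal cortex libraries entered another. The test was run on simulated counts with each comparison's means and library sizes, with 50 changed genes per fold (genes tested bracketed). At a 2-fold change it recovered 54% of changed genes for hippocampus against cortex in astrocyte-like cells (11309 genes), 66% in microglia-like (12537) and 78% in endothelial-like cells (10818), 14% for striatum against cortex (11296) and 12% against hippocampus (11339). For transgenic against wild type it recovered 90% in astrocyte-like (8664), 94% in microglia-like (11277), 90% in oligodendrocyte-like (8162) and 94% in endothelial-like cells (8937). At a 4-fold change the shares were 96%, 98%, 92%, 84%, 80%, 92%, 98%, 94% and 94% in the same order. Of simulated calls 1.92% to 7.45% were false. These rates hold for the simulated genes and libraries alone.

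The rule for genes named in the text was fixed before the data were examined. Per comparison it takes, among genes past the threshold with a mean of at least 20 CPM, the 10 with the largest rise and the 10 with the largest fall. It leaves out genes whose mean CPM in the class is under 1/5 of that in another named class of the same libraries, since free RNA of that class could set them. It also leaves out Xist, Tsix and Y-linked genes, predicted genes, and mitochondrial, ribosomal protein and haemoglobin genes. The 4 members of each gene list with the smallest adjusted p, and App and Prnp, could be named too. Some genes that these rules take are not reported here.

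Gene lists were fixed at the same time. Those for astrocyte-like cells cover astrocyte identity, reactive and disease-associated astrocytes, cholesterol synthesis, lipid transport, transmitter uptake and metabolism, potassium and ion transport, gap junctions and endfeet, receptors and calcium, synapse organising and secreted factors, process morphology and actin linkage, forebrain patterning factors and Alzheimer risk. Microglia-like cells had lists for homeostatic, stage 1 and stage 2 disease-associated microglia, Alzheimer risk, and cytokines and chemokines, oligodendrocyte-like cells for myelin proteins, cholesterol synthesis and disease-associated oligodendrocytes, endothelial-like cells for identity and barrier and for activation. All classes had lists for interferon response, antigen presentation and complement, immediate early and dissociation response, glycolysis, oxidative phosphorylation, unfolded protein response and lysosome, and background lists for neurons, oligodendrocytes, microglia, vessels, and choroid plexus and ependyma. The last was measured with enough members only in microglia-like and precursor-like cells of the young libraries. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated one, with adjustment over the lists of a comparison.

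Shares of cells in a class, and of cells with a UMI of a gene, were compared between libraries with two-sided exact permutation tests over all regroupings (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3), with Benjamini-Hochberg adjustment over the 17 classes. For the share of cells with a UMI each cell was thinned to 1000 UMIs by its exact expected value, and shallower cells were left out. A count of 0 was given the limit that 3 counts would set, and a gene with 1 to 3 UMIs in a group the ratio of pooled CPM with a 95% exact interval. Both cover counting error alone.

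Replicate numbers recur between groups. Whether they pair libraries was checked from the correlation of same-numbered libraries' deviations from their group means, before blocked and unblocked calls were compared. Between hippocampus and cortex every pair passed 0.1 in astrocyte-like (0.214 to 0.776), microglia-like (0.322 to 0.703) and endothelial-like cells (0.255 to 0.694; 6 pairs each) and in precursor-like cells (0.107 to 0.401; 5 pairs). Between genotypes all 9 pairs did in microglia-like (0.282 to 0.7), oligodendrocyte-like (0.12 to 0.646), endothelial-like (0.151 to 0.497) and precursor-like cells (0.206 to 0.68). The pairing is read from the data, as the labels give the number alone.

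Alternatives fixed in advance were DESeq2 1.42.0, RLE size factors, no low-count filter, doublets kept, at least 1000 UMIs with at most 10% mitochondrial UMIs, at most 200 cells per library and class, the replicate number as a block, leaving out each library, and the libraries with the larger feature table alone (for the young groups, those of Cell Ranger 6.0.0). For shares they were a logit scale with 0.5 added, sign flips within replicate numbers, thinning to 500 UMIs and no thinning. Chosen after seeing the data were leaving out clusters with a median UMI count under 0.5 of their libraries' median, leaving out 3 shallow libraries, the Cell Ranger version as a term, single Cell Ranger versions, and the comparisons in oligodendrocyte precursor-like cells. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.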

Results

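Dissociated cells of mouse brain were profiled in droplets with the 10x Genomics 3' assay, in which each captured transcript carries a unique molecular identifier (UMI) and is counted once. The series holds 34 libraries. Of these, 15 came from C57BL/6 mice, a common inbred strain, at 2 months of age: 7 of cortex, 6 of hippocampus and 2 of striatum. The other 19 came from frontal cortex at 10 to 11 months, 10 of them from APP/PS1dE9 transgenic mice, which carry a mutant human gene for amyloid precursor protein and form amyloid plaques, and 9 from wild-type controls of that line. Total UMIs of a library, in units of 1e6 and over all deposited barcodes, were 7.98 to 40.8 in cortex, 9.96 to 67.2 in hippocampus and 22.2 to 72.2 in striatum. They were 12.6 to 22.3 in wild-type and 12.1 to 28.3 in transgenic frontal cortex. The median kept cell held between 1507 and 8104.5 UMIs, depending on the library. Per the labels, libraries of a group are separate samples, but nothing says that each came from its own animal, so p-values measure the spread between libraries. UMI counts were summed per library and cell class, and a class is called X-like from markers fixed in advance. Levels are given in counts per 1e6 (CPM), with TMM-scaled library sizes in gene comparisons and unscaled ones in checks of labels and explanations, as mean ± SD over libraries, and coordinates refer to mm10.

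The genotype labels were checked on the genes of the transgene constructs. The constructs of this line are driven by the promoter of the mouse prion protein gene Prnp (chromosome 2, 131909928 to 131938429). In oligodendrocyte precursor-like cells Prnp stood at 1895 ± 257 CPM in transgenic libraries (n = 10) and 450.5 ± 59.1 in wild-type ones (n = 9), a ratio of 4.21, with 10 of 10 transgenic libraries above every wild-type one (exact permutation test, two-sided, adjusted p = 9.74e-05). The ratio was 1.80 in oligodendrocyte-like cells (adjusted p = 0.00013) and 2.46 in microglia-like cells (adjusted p = 9.74e-05), by the same exact permutation test and again with 10 of 10 libraries above. App, at 862.6 ± 212 against 464.9 ± 37.1 CPM in the precursor-like cells, had a ratio of 1.86 (10 of 10 libraries, exact permutation adjusted p = 0.000146). Over all cells neither Prnp nor App passed (exact permutation adjusted p = 0.0637 and 0.569). There 7 and 4 of 10 transgenic libraries lay above every wild-type one. App passed in no other class tested (0.0593 to 0.822), nor Prnp in astrocyte-like and endothelial-like cells (0.548 and 0.569).

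The title of the series places regional diversity of astrocytes at its centre, and hippocampus against cortex is the regional comparison with the most libraries. Hippocampal astrocyte-like cells carried more RNA for Gfap, the intermediate filament of astrocytes, for the matrix protein Thbs4 (thrombospondin 4), complement component C4b and angiotensinogen (Agt). They carried less RNA for the retinoid isomerase Rpe65, the carbonic anhydrase-related protein Car8, the vesicle-priming factor Unc13c, the secreted bone morphogenetic protein antagonist Chrdl1 and the GABA-B receptor subunit Gabbr2. Gfap (chromosome 11, 102887336 to 102900912) reached 737.0 ± 136 CPM in hippocampus (n = 6) against 102.8 ± 60.0 in cortex (n = 7), a log2 change of 2.88 (SE 0.38, edgeR adjusted p = 3.38e-05). Thbs4 (chromosome 13, 92751590 to 92794818) stood at 210.3 ± 51.9 against 27.9 ± 25.2 CPM, a log2 change of 3.18 (SE 0.39, adjusted p = 1.43e-05). C4b (chromosome 17, 34728380 to 34743882) stood at 180.4 ± 57.9 against 25.9 ± 8.33 CPM (log2 change 2.89, SE 0.25, adjusted p = 3.66e-07). Chrdl1 (chromosome X, 143285674 to 143394262) lay at 17.5 ± 5.44 against 178.5 ± 40.5 CPM, a log2 change of -3.37 (SE 0.23, adjusted p = 3.35e-08). For each of these 4 genes all 6 hippocampal libraries lay on one side of all 7 cortical ones.

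**Figure D1:**
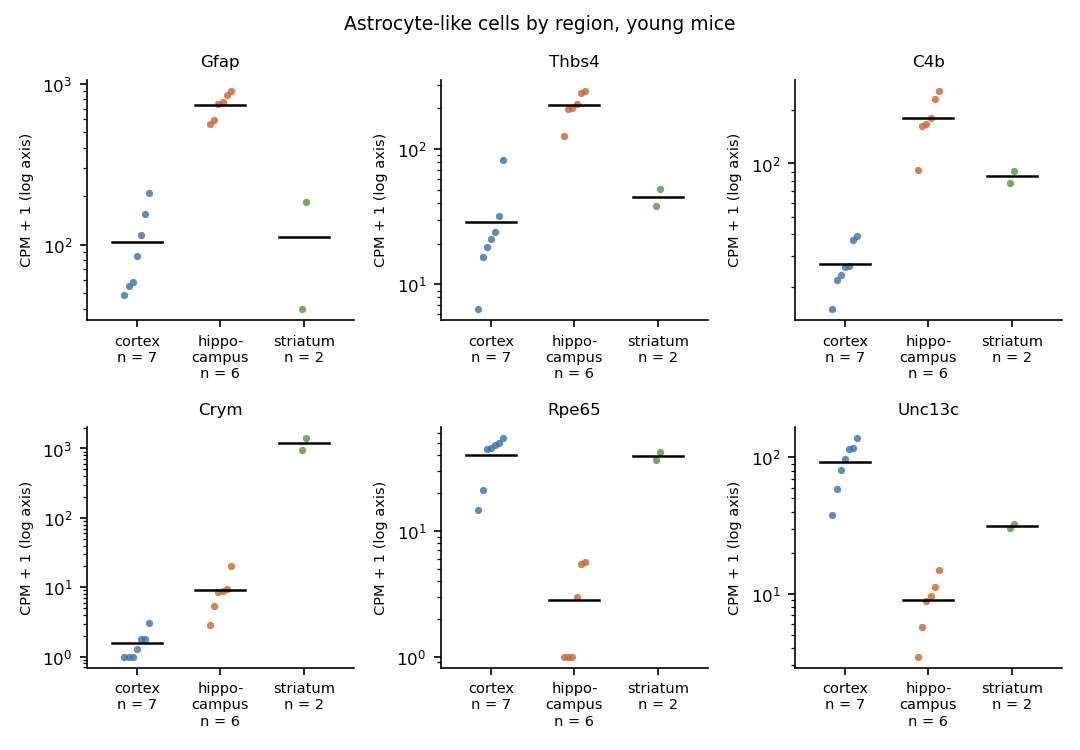
CPM + 1 on a log axis for 6 genes in astrocyte-like cells of the young libraries; each point is a library and each bar the mean of 7 cortical, 6 hippocampal or 2 striatal libraries. Gfap, Thbs4 and C4b sit higher in every hippocampal library than in every cortical one, Rpe65 and Unc13c lower, and Crym reaches a mean of 1184 CPM in striatum.

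The other named genes that rose in hippocampus were Agt (log2 change 2.30), the citrullinating enzyme Padi2 (2.00), the matrix protein Tnc (2.00), Kcne1l (1.99), the semaphorin receptor Nrp2 (1.957) and Icosl (1.88). Those that fell were Rpe65 (-4.14), Car8 (-4.06), Unc13c (-3.49), Gabbr2 (-3.36), Pdzph1 (-3.18), the R-spondin receptor Lgr6 (-2.66), Eogt (-2.55), Tox (-2.52) and the G protein regulator Rgs7 (-2.51), with edgeR adjusted p from 3.28e-07 to 0.00032 over these 15 genes. Of 11655 genes tested, 871 rose and 520 fell. Among the risen genes 237, and among the fallen ones 409, were not more than 5 times as abundant in another named class of the same libraries. The others can be set by RNA that leaked from those classes. Clusters 10 (48.94% of the class) and 5 (33.36%) held most cortical cells of the class, clusters 5 (57.4%) and 28 (20.81%) most hippocampal ones. Median UMI counts were 0.324 (cluster 5), 1.244 (10) and 1.1 (28) of their libraries' median, so depth differed with region. With the replicate number as a block 2730 genes passed, without cortex replicate 0 it was 2297, and in the Cell Ranger 6.0.0 libraries alone, a single upstream version, 2770. The count was 685 with at most 200 cells per library.

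Among the gene lists fixed in advance, disease-associated astrocyte genes moved up in hippocampus: 13 of 20 measured members rose and 7 did not pass (16 rose adjusted over the list alone), among them C4b, Gfap and Thbs4 (camera adjusted p = 5.31e-14, adjusted p = 0.0328 with an estimated correlation). Of the reactive astrocyte genes 10 of 14 rose (11 adjusted over the list alone), including the asparaginase Aspg (log2 change 2.49) and the serine protease inhibitor Serpina3n (2.24), with camera adjusted p = 9.64e-13 and adjusted p = 0.0254 with an estimated correlation. Both lists hold genes of other cells, since 7 and 11 of their members were more than 5 times as abundant in another class. Oligodendrocyte background genes, which astrocytes barely express, rose too: 12 of 15 passed (15 adjusted over the list alone), with a median log2 change of 2.18 (camera adjusted p = 8.31e-18, adjusted p = 0.033 with an estimated correlation). Neuron background genes rose in 8 of 20 (9 adjusted over the list alone, camera adjusted p = 1.35e-06, and 0.204 with an estimated correlation). Antigen presentation and complement genes rose in 8 of 14 (9 adjusted over the list alone; camera adjusted p = 8.06e-07, adjusted p = 0.202 with an estimated correlation), and 12 of the 14 were more than 5 times as abundant elsewhere.

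Genes of cholesterol synthesis moved down in hippocampus: 5 of 23 fell and 18 did not pass (1 risen and 6 fallen adjusted over the list alone), with Hsd17b7 (log2 change -0.94), Msmo1 (-0.91) and the sterol sensor Insig1 (-0.78) among them (camera adjusted p = 0.000358, adjusted p = 0.327 with an estimated correlation). Of the genes for transmitter uptake and metabolism 3 of 16 fell (4 adjusted over the list alone), such as the glutamine transporter Slc38a3 (-0.84; camera adjusted p = 0.0216, adjusted p = 0.202 with an estimated correlation). Receptor and calcium genes split, with 3 of 22 risen and 7 fallen (3 and 9 adjusted over the list alone; camera adjusted p = 0.0268 downwards, adjusted p = 0.204 with an estimated correlation). Forebrain patterning transcription factors split as well, 9 of 25 risen and 5 fallen (10 and 5 adjusted over the list alone). Meis1 (-1.84), Meis2 (-1.67) and Hes5 (-1.03) fell and Fezf2 (1.14) rose (camera adjusted p = 0.00718 upwards, adjusted p = 0.204 with an estimated correlation). Alzheimer risk genes rose in 7 of 30 and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0364, adjusted p = 0.204 with an estimated correlation). Interferon response genes rose in 2 of 17 (4 adjusted over the list alone, camera adjusted p = 0.0364, and 0.435 with an estimated correlation). Of 24 alternative settings, 8 ended the call for Alzheimer risk and 6 that for interferon response.

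The remaining lists passed no test in this comparison, with camera adjusted p from 0.235 to 0.942. Glycolysis had 1 of 23 members risen and 2 fallen. Among 21 identity genes 1 rose, the water channel Aqp4 (log2 change 0.66), and 1 fell, Aldh1l1 (-0.69), and neither passed adjusted over the list alone. The call for Aqp4 ended without any 1 of 12 libraries. Microglia background and oxidative phosphorylation had no member past the threshold among 15 and 35, also when adjusted over the list alone. Process morphology and actin linkage had 5 of 23 risen and 2 fallen, lipid transport 2 and 1 of 15, immediate early and dissociation response 1 and 1 of 19, synapse organising and secreted factors 5 and 4 of 23. Vascular background had 2 risen and 1 fallen of 15, potassium and ion transport 1 and 2 of 15, lysosome 1 and 2 of 27, gap junction and endfoot 1 and 0 of 16, and unfolded protein response 1 and 1 of 18. Adjusted over the list alone these counts became 5 and 3 for process morphology, 3 and 1 for lipid transport, 2 and 2 for potassium and ion transport, 0 and 1 for lysosome and 2 and 0 for gap junction and endfoot. Median, mean and test differed in sign for process morphology (median log2 change -0.10, mean 0.17, test upwards), for potassium and ion transport (median 0.06) and for the unfolded protein response (median 0.01, mean -0.03, test downwards).

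Microglia-like and endothelial-like cells of the same libraries share the dissection and the leaked RNA but not the lineage. In microglia-like cells the Toll-like receptor gene Tlr12 fell in hippocampus, to 17.3 ± 1.93 from 29.0 ± 4.54 CPM (log2 change -0.76, SE 0.12, edgeR adjusted p = 0.00263), in 6 of 6 libraries. Pcbd2 rose by a log2 change of 0.59 (SE 0.13, adjusted p = 0.0286; 6 of 6 libraries above all 7), and Tnfsf13b, a B cell survival cytokine, by 0.71 (SE 0.18, adjusted p = 0.0481; ranges overlapped). In all, 231 genes rose and 5 fell of 12914, but only 2 and 2 of these were not more than 5 times as abundant in another class. With the replicate block 364 rose and 94 fell, and in Cell Ranger 6.0.0 libraries alone 347 and 43. Tlr12 lost its call with at most 200 cells per library, where 38 genes passed. Tnfsf13b lost its call without any 1 of 11 libraries, Pcbd2 without any 1 of 6.

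In endothelial-like cells the protease Htra3 stood at 44.0 ± 20.3 against 18.8 ± 5.97 CPM (log2 change 1.24, SE 0.25, edgeR adjusted p = 0.025; 6 of 6 libraries above all 7) and the homeobox gene Meox1 at 32.1 ± 5.02 against 18.2 ± 7.09 (log2 change 0.90, SE 0.18, adjusted p = 0.0242; ranges overlapped). Of 11141 genes 58 rose and 0 fell by edgeR (743 at an unadjusted p under 0.05), while DESeq2 called 89 risen and 6 fallen, and 3 of the 58 were not more than 5 times as abundant elsewhere. The replicate block gave 161 risen and 54 fallen, and the Cell Ranger 6.0.0 libraries alone 108 and 12. The count fell to 29 without cortex replicate 2, 31 without cortex replicate 3, and 35, 32 and 26 without hippocampus replicates 2, 4 and 6. Htra3 lost its call without any 1 of 6 libraries (cortex replicates 1, 2, 5 and 6, hippocampus replicates 4 and 6) and Meox1 without any 1 of 4 (cortex replicate 2, hippocampus replicates 1, 4 and 6).

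Oligodendrocyte background genes rose in both of these classes. In microglia-like cells 12 of 15 rose (14 adjusted over the list alone; median log2 change 1.85; camera adjusted p = 6.83e-33, adjusted p = 0.00521 with an estimated correlation), in endothelial-like cells 11 of 15 (13 adjusted over the list alone; median 1.77; camera adjusted p = 5.78e-49, adjusted p = 0.000206 with an estimated correlation). Choroid plexus and ependymal background genes rose in 3 of 5 in microglia-like cells (4 adjusted over the list alone; camera adjusted p = 8.66e-10, adjusted p = 0.0249 with an estimated correlation). Cytokines and chemokines rose in 3 of 19 there (7 adjusted over the list alone; camera adjusted p = 6.83e-07, adjusted p = 0.0364 with an estimated correlation). The 3 were Spp1, Cxcl10 and Igf1, each more than 5 times as abundant in another class. Of the stage 2 disease-associated microglia genes 5 of 20 rose (6 adjusted over the list alone; camera adjusted p = 2.39e-06, adjusted p = 0.151 with an estimated correlation).

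Further lists in microglia-like cells passed camera with no member past the threshold over all genes. Immediate early and dissociation response (28 members, 1 risen adjusted over the list alone) had camera adjusted p = 0.0031 (0.167 with an estimated correlation). Oxidative phosphorylation (35 members) had 0.0168 and 0.759. Neuron background (20 members, 3 risen and 1 fallen adjusted over the list alone) had 0.0187 and 0.668. Downwards, vascular background (16 members) had 0.0428 and 0.668. In endothelial-like cells the same held for neuron background (20 members, camera adjusted p = 0.00605, adjusted p = 0.549 with an estimated correlation) and oxidative phosphorylation (35 members, 0.0365, and adjusted p = 0.956). Microglia background (15 members, 0.00858 and 0.779) and antigen presentation (12, 0.0188 and 0.549) moved downwards. Of 24 alternative settings, 11 ended the call for vascular background and 5 that for neuron background in microglia-like cells. In endothelial-like cells 13 ended that for oxidative phosphorylation, which reversed in 1 more, 8 that for antigen presentation and 5 that for microglia background. The lists of homeostatic microglia, stage 1 disease-associated microglia, Alzheimer risk genes of microglia, antigen presentation, glycolysis, microglia background, lysosome, interferon response (1 of 20 risen; median log2 change -0.03, mean 0.32, test downwards) and unfolded protein response passed no test in microglia-like cells (camera adjusted p 0.0735 to 0.645). Neither did endothelial identity and barrier, endothelial activation, glycolysis, vascular background, immediate early response, lysosome, interferon and unfolded protein response in endothelial-like cells (0.298 to 0.966). Median, mean and test differed in sign there for immediate early response, interferon and endothelial activation.

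Striatal astrocyte-like cells were marked by Crym, which encodes a thyroid hormone-binding crystallin. Crym (chromosome 7, 120186380 to 120202111) stood at 1184 ± 315 CPM in striatum (n = 2), 0.572 ± 0.763 in cortex and 8.27 ± 6.09 in hippocampus, a log2 change of 11.05 against cortex (SE 0.56, edgeR adjusted p = 3.63e-10) and 7.09 against hippocampus (SE 0.48, adjusted p = 3.75e-08). The homeobox gene Six3 (chromosome 17, 85613608 to 85629302) had 569 UMIs in striatal cells of the class and 3 in cortical ones. Its ratio of pooled CPM is 760.9 (95% counting interval 259 to 3700), and against hippocampus its log2 change was 6.85 (SE 0.43, adjusted p = 3.41e-08). The protease gene Prss56 reached 45.7 ± 6.28 CPM, a log2 change of 4.80 against cortex (SE 0.47, adjusted p = 2.11e-05). No Prss56 UMI was seen in the 6 hippocampal libraries, and with a floor of 3 UMIs over that group it was at least 122.9-fold higher in striatum. Hopx, a homeodomain-only protein, stood at 39.2 CPM against 294.1 ± 110 in cortex (log2 change -2.91, SE 0.58, adjusted p = 0.00343) and 820.5 ± 310 in hippocampus (-4.39, SE 0.63, adjusted p = 0.000317).

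Against cortex, 483 genes rose and 165 fell of 11655, and 69 and 125 of these were not more than 5 times as abundant in another class. Further named genes that rose were Lmo1 (log2 change 2.66), the Wnt receptor Fzd5 (2.29), Lrrc9 (2.08), Kcne1l (1.92), C4b (1.78) and the kinesin Kif21a (1.37). Those that fell were Lgr6 (-3.74), the mitochondrial glutamate carrier Slc25a18 (-3.44), myocilin (Myoc, -3.27), Dmrta2 (-3.18), Ptchd4 (-2.81), the potassium channel Kcnj16 (-2.37), Chrdl1 (-2.16), the growth factor antagonist Spry2 (-2.13) and connexin 30 (Gjb6, -1.98), with edgeR adjusted p from 1.96e-05 to 0.0307 over these 15 genes. Against hippocampus, 214 rose and 195 fell, 79 and 102 of them not more than 5 times as abundant elsewhere. Risen there were also Rpe65 (4.02), Gabbr2 (3.19), Pdzph1 (3.00), Lmo1 (2.92), Shisa9 (2.91), Lrrc9 (2.74) and the GDNF receptor Gfra1 (2.74). Fallen were Myoc (-4.38), Gpd1 (-3.00), Dmrta2 (-2.97), Nrp2 (-2.85), Slc25a18 (-2.74), Gfap (-2.73), Hsd11b1 (-2.70), Thrsp (-2.36) and Agt (-2.32), with adjusted p from 2.36e-06 to 0.041.

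Both striatal comparisons rest on 2 libraries. Without striatum replicate 5 the calls against cortex fell to 123, and Fzd5, Lrrc9, Kcne1l, Kif21a, Slc25a18, Dmrta2, Hopx, Kcnj16, Spry2 and Gjb6 lost theirs; without cortex replicate 0 there were 1048. Kif21a, Myoc, Hopx, Spry2 and Gjb6 lost their calls without striatum replicate 4, and Kif21a also without cortex replicate 3, 4 or 5. Against hippocampus the calls were 104 without striatum replicate 5, 167 without striatum replicate 4 and 628 without cortex replicate 0, and without replicate 4 the named fallen genes other than Hopx lost their calls. Of these, Gpd1, Dmrta2, Slc25a18, Hsd11b1, Thrsp and Agt also lost theirs without replicate 5, and Agt without any 1 of 11 libraries in all. In the Cell Ranger 6.0.0 libraries alone 1690 and 967 genes passed. Cluster 40 held 43.23% of the striatal class and cluster 5 another 36.92%.

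Against cortex, neuron background genes rose in 10 of 20 and fell in 1 (11 and 2 adjusted over the list alone; median log2 change 2.27; camera adjusted p = 6.07e-17, adjusted p = 0.156 with an estimated correlation). Oligodendrocyte background genes rose in 8 of 15 (12 adjusted over the list alone, camera adjusted p = 1.04e-11, and 0.197 with an estimated correlation). Cholesterol synthesis genes fell in 4 of 23 (8 adjusted over the list alone), among them Insig1 (-1.54), Dhcr7 (-1.49) and Msmo1 (-1.07; camera adjusted p = 1.32e-07, adjusted p = 0.24 with an estimated correlation). Astrocyte identity fell in 1 of 21 (2 adjusted over the list alone, camera adjusted p = 0.00469, and 0.24 with an estimated correlation). In potassium and ion transport Kcnj16 and the chloride channel Clcn2 (-1.69) fell and 1 of 15 rose (1 and 6 adjusted over the list alone; camera adjusted p = 0.0237, adjusted p = 0.197 with an estimated correlation). Forebrain patterning factors split evenly, 5 of 25 risen and 5 fallen, with Otx1 at -1.90, and passed no test (camera adjusted p = 0.204). The other 18 lists also passed none (0.0944 to 0.91), among them disease-associated astrocyte with 3 of 20 risen and 1 fallen and reactive astrocyte with 1 of 14 risen. In that list Serpina3n rose by 1.86 (edgeR adjusted p = 0.0363), but without striatum replicate 5 its log2 change was -0.06. Without that library Insig1, Dhcr7, Msmo1, Clcn2 and Otx1 lost their calls too. Adjusted over the list alone, 3 reactive astrocyte genes rose, transmitter uptake had 1 risen and 5 fallen of 16 (0 and 2 over all genes), and synapse organising factors 2 and 3 of 23 (2 and 1 over all genes). Median and test, or mean and test, differed in sign for process morphology, immediate early response, vascular background, Alzheimer risk and unfolded protein response.

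Against hippocampus, reactive astrocyte genes fell in 5 of 14 (7 adjusted over the list alone; median log2 change -1.25; camera adjusted p = 3.58e-07, adjusted p = 0.0427 with an estimated correlation). Disease-associated astrocyte genes fell in 3 of 20, Hopx, Gfap and Thbs4 (-2.27; 5 adjusted over the list alone; camera adjusted p = 7.65e-07, adjusted p = 0.179 with an estimated correlation). Antigen presentation genes fell in 3 of 14 (6 adjusted over the list alone, camera adjusted p = 1.35e-06, and 0.179 with an estimated correlation). Neuron background genes rose in 7 of 20 and fell in 3 (8 and 4 adjusted over the list alone; camera adjusted p = 4.85e-05, adjusted p = 0.318 with an estimated correlation). Interferon response fell in 2 of 17 (adjusted p = 0.00499, and 0.314 with an estimated correlation), potassium and ion transport in 3 of 15 (0.0163 and 0.179), and synapse organising factors rose in 1 of 23 and fell in 2 (0.0342 and 0.314). Identity, cholesterol synthesis and lysosome genes passed camera downwards with no member past the threshold (adjusted p = 0.0163, 0.0234 and 0.0425, and 0.314, 0.542 and 0.542 with an estimated correlation). The calls for synapse organising factors and lysosome each ended in 6 of 24 alternative settings. Forebrain patterning factors rose in 4 of 25 and fell in 10 (7 and 12 adjusted over the list alone) without a set call (0.356), and the other 13 lists made none either (0.0632 to 0.985), with median and test of opposite sign for immediate early response and glycolysis.

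The share of astrocyte-like cells with a Gfap UMI was measured with each cell thinned to 1000 UMIs. It was 33.8% ± 2.66 in hippocampus (SD, n = 6, range 31.0 to 37.9) and 6.33% ± 2.50 in cortex (n = 7, range 4.01 to 10.6), two-sided exact permutation p = 0.000583, the smallest that 1716 regroupings can give. Microglia-like cells, which lack Gfap, gave 1.01% ± 0.862 and 0.194% ± 0.129. Thinning left out 32.99% of hippocampal and 13.41% of cortical cells of the class. Unthinned shares were 43.3% and 14.2%, at library medians of 985 to 1735 UMIs per astrocyte-like cell in hippocampus and 1008 to 7497.5 in cortex, and of 2903 to 5234 and 1339 to 6911 per microglia-like cell. In Cell Ranger 6.0.0 libraries alone the shares were 32.9% (n = 5) and 5.62% (n = 6), exact permutation p = 0.002165, the smallest of 462 regroupings. Sign flips within replicate numbers kept the direction in 6 of 6 pairs, with p = 0.03125, the smallest exact p that 64 flips can give.

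**Figure D2:**
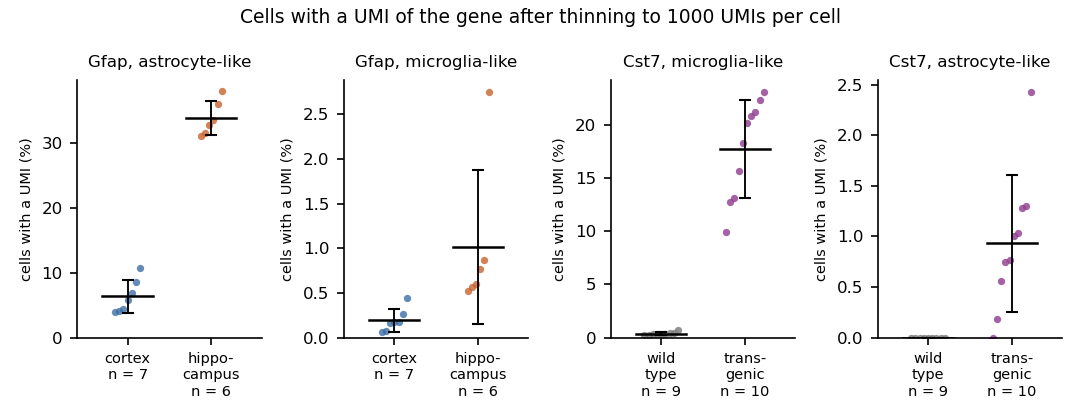
Percent of cells with a UMI of Gfap or Cst7 after thinning to 1000 UMIs per cell, in the class of interest and in a class that should lack the gene; points are libraries, bars the mean and whiskers 1 SD. Gfap was seen in 33.8% of hippocampal and 6.33% of cortical astrocyte-like cells, and Cst7 in 17.7% of transgenic and 0.370% of wild-type microglia-like cells.

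The make-up of the kept cells also differed between the regions. Oligodendrocyte-like cells made up 26.5% ± 9.03 in hippocampus and 5.72% ± 2.13 in cortex, and immature neuron-like cells 2.81% ± 0.7502 and 0.151% ± 0.144 (exact permutation adjusted p = 0.0033 for each; all 6 libraries above all 7). Ependymal-like cells made up 0.760% ± 0.427 in hippocampus and were absent among 28961 cortical cells, which allows up to 0.0104% (exact permutation adjusted p = 0.0033). Pericyte-like cells were fewer in hippocampus, 2.77% ± 0.884 against 5.59% ± 1.13 (exact permutation adjusted p = 0.00991), as were endothelial-like cells, 7.87% ± 3.22 against 15.4% ± 3.69 (adjusted p = 0.0139, overlapping). Astrocyte-like cells, at 10.5% ± 6.74 and 17.4% ± 11.4 (0.383), and 11 further classes did not pass. The 5 calls became 9 in Cell Ranger 6.0.0 libraries alone and 0 under sign flips within replicate numbers, where the exact permutation p cannot go below 0.03125 before adjustment. Dissection and filtering can set such shares.

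In the amyloid model the response of microglia-like cells was the broadest. Transgenic microglia-like cells gained the cysteine protease inhibitor cystatin F (Cst7), the class II antigen presentation genes H2-Aa and Cd74, osteopontin (Spp1), galectin 3 (Lgals3), lipoprotein lipase (Lpl) and the integrin Itgax. Cst7 (chromosome 2, 150570415 to 150578944) stood at 623.4 ± 174 CPM in transgenic (n = 10) and 4.53 ± 1.98 in wild-type libraries (n = 9), a log2 change of 7.09 (SE 0.25, edgeR adjusted p = 2.17e-15). Itgax (chromosome 7, 128129547 to 128150657) stood at 114.0 ± 25.9 against 7.03 ± 1.73 CPM (log2 change 4.04, SE 0.16, adjusted p = 1.2e-14), and Cd74 at 522.9 ± 237 against 18.0 ± 3.69 (4.86, SE 0.23, adjusted p = 5.44e-13). For these 3 genes 10 of 10 transgenic libraries lay above all 9 wild-type ones. H2-Aa rose by 6.46, Spp1 by 5.60, Lgals3 by 5.60, Lpl by 4.99, Lyzl4 by 4.76, the growth factor Csf1 by 3.70 and Cox6a2 by 3.47. Falls among named genes were smaller: the integrin Itga9 (-0.95, SE 0.11, adjusted p = 4.31e-07), Serpinf1 (-0.81), S100a10 (-0.76), Il7r (-0.69), Lbr (-0.69), Dok3 (-0.67), Bank1 (-0.67), Ggta1 (-0.63), Kdm6b (-0.62) and Mtss1 (-0.61).

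**Figure D3:**
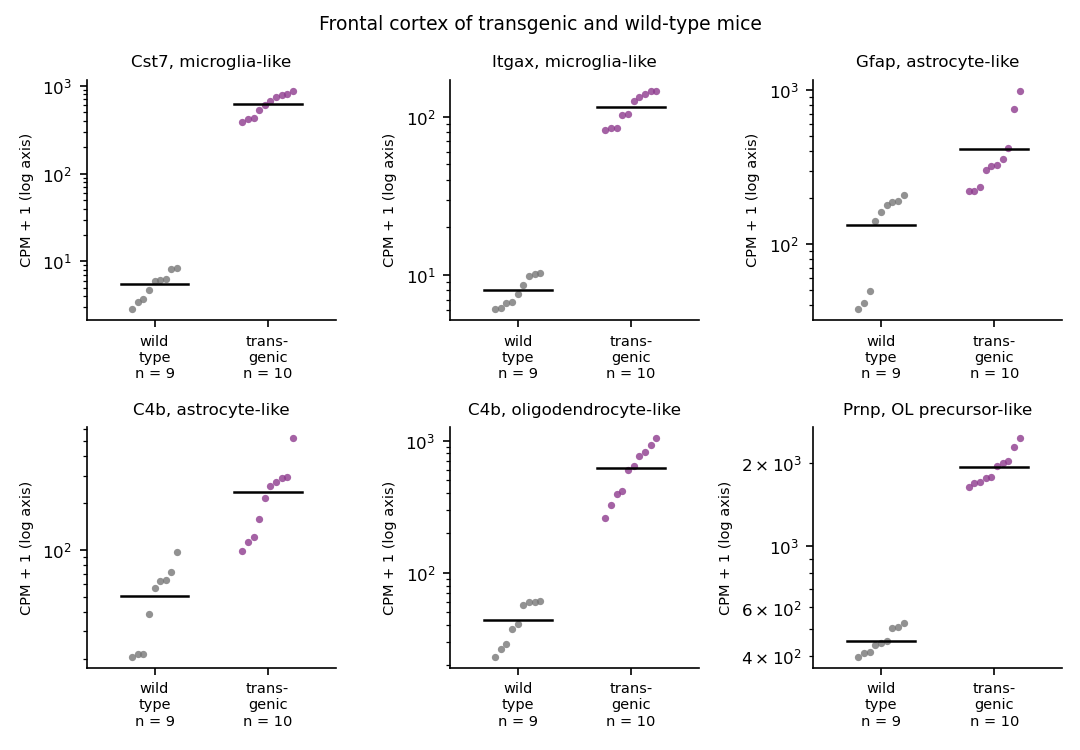
CPM + 1 on a log axis for 5 genes in named classes of frontal cortex; each point is a library, each bar the mean of 9 wild-type or 10 transgenic libraries. In all 6 panels every transgenic library sits above every wild-type one, from a mean of 623.4 against 4.53 CPM for Cst7 in microglia-like cells to 413.2 against 131.3 for Gfap in astrocyte-like cells.

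Of 11354 genes 1287 rose and 827 fell, and 918 and 679 of these were not more than 5 times as abundant in another class. The replicate block gave 2051 and 1973. Within Cell Ranger 5.0.0 libraries 955 genes rose and 410 fell, and within the 5 libraries of 4.0.0, 251 and 8. Cluster 1 held 49.47% of the class in transgenic and 78.53% in wild-type mice, and cluster 9 held 31.78% and 0.79%. All 21 stage 2 disease-associated microglia genes rose (21 adjusted over the list alone; camera adjusted p = 7.98e-92, adjusted p = 1.11e-05 with an estimated correlation), as did all 8 of stage 1 (8 adjusted over the list alone; 1.34e-27, and adjusted p = 0.000774 with an estimated correlation). Both lists were drawn up from mouse models of amyloid disease. Lysosome genes rose in 22 of 27 (22 adjusted over the list alone, 1.13e-22 and 0.0203). Cytokines and chemokines rose in 13 of 19 (14, 1.88e-22 and 0.000552). Antigen presentation and complement genes rose in 11 of 18 (13, 3.14e-21 and 0.00383).

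Oxidative phosphorylation genes rose in 24 of 35 (26 adjusted over the list alone, camera adjusted p = 2.38e-09, and 0.268 with an estimated correlation). Glycolysis genes rose in 11 of 20 with 2 fallen (12 and 3 adjusted over the list alone, 0.000211 and 0.118). Homeostatic microglia genes fell in 9 of 21 and rose in 1 (11 and 1 adjusted over the list alone), with Txnip at -0.59, the CSF1 receptor Csf1r at -0.35, Tmem119 at -0.32 and the purinergic receptor P2ry12 at -0.27 (camera adjusted p = 0.00143, adjusted p = 0.12 with an estimated correlation). Interferon genes rose in 3 of 20 (3 adjusted over the list alone, 0.00153 and 0.483). Immediate early genes rose in 5 of 25 with 2 fallen (5 and 2 adjusted over the list alone, 0.0143 and 0.33). The chemokines Ccl3 and Ccl4 in that list rose by 3.38 each. The call for immediate early genes ended in 7 of 29 alternative settings. Alzheimer risk genes of microglia split, 6 of 25 risen and 5 fallen, with Ctsb at 1.30, Tyrobp at 0.97 and Trem2 at 0.91 (7 and 5 adjusted over the list alone; camera adjusted p = 0.111; median -0.06, mean 0.28, test upwards). Microglia background (5 of 15 risen, 3 fallen), unfolded protein response (3 of 18 risen), vascular background (1 of 13), oligodendrocyte background (0 of 14) and neuron background (0 of 12) passed no test (0.189 to 0.885).

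The share of microglia-like cells with a Cst7 UMI, thinned to 1000 UMIs, was 17.7% ± 4.58 in transgenic libraries (SD, n = 10, range 9.94 to 23.1) and 0.370% ± 0.142 in wild-type ones (n = 9), two-sided exact permutation p = 1.1e-05, the smallest that 92378 regroupings can give. Astrocyte-like cells gave 0.930% ± 0.676 in transgenic libraries (1.75% unthinned), and none of 2692 unthinned wild-type cells had a Cst7 UMI, which allows up to 0.1114%. Unthinned shares were 32.9% and 2.07%, and thinning left out 2.42% and 2.96% of microglia-like cells, whose library medians were 5110.5 to 10301.5 and 5070.5 to 8644.5 UMIs, against 1786 to 3291.5 and 2445 to 4443 in astrocyte-like cells. Within Cell Ranger 5.0.0 libraries the shares were 17.8% and 0.401% (n = 7 each, exact permutation p = 0.000583, the smallest of 3432 regroupings), and sign flips within replicate numbers gave an exact p = 0.003906, the smallest of 512.

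Without a replicate block, astrocyte-like cells of the transgenic mice changed in few genes, all of them upwards. With the block more genes passed, falls among them, as given below with the correlations of the pairs. C4b stood at 233.4 ± 127 CPM in transgenic and 49.6 ± 26.9 in wild-type libraries (log2 change 2.25, SE 0.29, edgeR adjusted p = 5.46e-05) and Gfap at 413.2 ± 254 against 131.3 ± 69.9 (1.66, SE 0.31, adjusted p = 0.00759), each in 10 of 10 libraries. The collagen Col16a1 rose by 1.14 (SE 0.20, adjusted p = 0.00268), the urea transporter Slc14a1 by 1.05 (0.00268), Csf1 by 0.65 (0.0137) and the kinesin Kifc3 by 0.52 (0.0266), whose call ended without any 1 of 6 libraries. Aspg (1.87, adjusted p = 0.00135) and Serpina3n (1.67, adjusted p = 0.00268) rose from low levels. In all 12 genes rose and 0 fell of 8762 by edgeR (426 unadjusted), and DESeq2 called 17 and 0. Of the 12, 8 were not more than 5 times as abundant in another class. The Cell Ranger 5.0.0 libraries alone gave 12 risen and 1 fallen, the 5 libraries of 4.0.0 gave 0 (268 unadjusted), with C4b at 1.58. Without the clusters of low UMI count, 15 libraries remained and 0 genes passed (667 unadjusted), with C4b at 1.55 and Gfap at 1.32. Clusters 5 and 10 held 55.39% and 29.6% of the class in transgenic and 48.92% and 41.05% in wild-type libraries.

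Reactive astrocyte genes rose in 3 of 6 measured (5 adjusted over the list alone, camera adjusted p = 9.34e-18, 0.000789 with an estimated correlation). Disease-associated astrocyte genes rose in 3 of 16 (6 adjusted over the list alone, 2.87e-14 and 0.0218). Antigen presentation and complement genes rose in 2 of 9 (7 adjusted over the list alone, 2.22e-19 and 0.000391). Microglia background genes moved with them: 1 of 13 rose, Trem2 (7 adjusted over the list alone; median log2 change 0.54; 2.87e-14, and adjusted p = 0.0357), and all 13 are more than 5 times as abundant in another class. Oligodendrocyte background (6 members, 4 adjusted over the list alone; 8.35e-05, and adjusted p = 0.0408) and neuron background genes (7 members, 3 adjusted over the list alone; 0.000106, and adjusted p = 0.0278) passed camera upwards with no member past the threshold over all genes. Alzheimer risk genes rose in 1 of 25 (2 adjusted over the list alone; 0.00249, and adjusted p = 0.0357). Forebrain patterning factors (15 members; 2.22e-05, and adjusted p = 0.0218) and process morphology (20 members, 1 fallen adjusted over the list alone; 0.00507, and adjusted p = 0.0218) moved downwards with no member past the threshold.

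Cholesterol synthesis (23 members, median -0.24, camera adjusted p = 1.19e-11, 0.0512 with an estimated correlation) moved downwards with no member past the threshold. So did oxidative phosphorylation (35 members, 9.75e-06 and 0.417). Interferon response (9 members, 5 adjusted over the list alone, 9.75e-06 and 0.0547) moved upwards, again with no member past the threshold. So did lysosome (26 members, 3 adjusted over the list alone, 2.22e-05 and 0.123). Identity, gap junction and endfoot, immediate early response, unfolded protein response, glycolysis, receptors and calcium, transmitter uptake, lipid transport, potassium and ion transport, synapse organising factors and vascular background passed no test (0.0975 to 0.904). Median and test differed in sign for receptors and calcium and for identity.

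Oligodendrocyte-like cells of the transgenic mice gained C4b, at 617.1 ± 267 against 42.9 ± 15.8 CPM (log2 change 3.85, SE 0.26, edgeR adjusted p = 1.08e-10), and Serpina3n (chromosome 12, 104406729 to 104414329), at 91.0 ± 34.9 against 9.02 ± 2.45 (3.31, SE 0.25, adjusted p = 4.72e-10), each in 10 of 10 libraries. Prnp rose by 0.86 (SE 0.08, adjusted p = 1.23e-07), Cela1 by 0.83 (0.0146), Rassf4 by 0.74 (0.0428) and the transcription factor Stat3 by 0.72 (0.00448). Kctd3 fell by 0.47 on the log2 scale (0.0197). The call for Rassf4 ended without any 1 of 15 libraries, that for Kctd3 without wild-type replicate 6. Of 8354 genes 18 rose and 1 fell, 8 and 1 of them not more than 5 times as abundant in another class. The replicate block gave 56 and 23, Cell Ranger 5.0.0 libraries alone 14 and 0, and 4.0.0 libraries alone 6 and 0 (236 unadjusted, edgeR). Disease-associated oligodendrocyte genes rose in 4 of 17: C4b, Serpina3n, H2-D1 (1.89) and B2m (0.97; 7 adjusted over the list alone; camera adjusted p = 8.83e-32, adjusted p = 3.6e-06 with an estimated correlation). Antigen presentation and complement genes rose in 3 of 8 (4 adjusted over the list alone; 7.94e-26, and adjusted p = 0.00019). Clusters 15 and 13 held most of the class in both genotypes.

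Further lists in oligodendrocyte-like cells passed camera upwards with no member past the threshold: lysosome (25 members, camera adjusted p = 3.09e-06, adjusted p = 0.121 with an estimated correlation), cholesterol synthesis (22; 2.59e-05 and 0.112), oligodendrocyte background (15; 0.000537 and 0.0525), microglia background (9; 2 adjusted over the list alone; 0.000755 and 0.284), oxidative phosphorylation (35; 0.00147 and 0.379), myelin proteins (19; 0.0151 and 0.112), interferon response (5; 0.02 and 0.0731), unfolded protein response (17; 0.0344 and 0.379) and neuron background (5; 0.0344 and 0.121). The call for the unfolded protein response ended with the replicate block (adjusted p = 0.143). Of 29 alternative settings, 10 ended that call, which reversed in 1 more, and neuron background lost its own in 10. Glycolysis (18 members) and immediate early response (1 of 14 risen, Cebpd; median -0.06, mean 0.03) passed no test (0.102 and 0.616).

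In endothelial-like cells of the transgenic mice 1 gene of 9066 rose, the neuronal kinesin Kif5a (log2 change 1.92), which is more than 5 times as abundant in another class and was named after its value was seen. By edgeR 0 fell (274 unadjusted), and DESeq2 also called 1 and 0. The replicate block gave 5 risen and 16 fallen. The call ended without any 1 of 16 libraries. No list had a member past the threshold. Microglia background (14 members, 4 adjusted over the list alone; camera adjusted p = 1.65e-15, adjusted p = 0.236 with an estimated correlation), lysosome (27, 2 adjusted over the list alone; 0.00139 and 0.241), antigen presentation (12; 0.00207 and 0.241), oxidative phosphorylation (35; 0.00245 and 0.435), neuron background (5, 1 adjusted over the list alone; 0.00292 and 0.238), interferon (20; 0.00474 and 0.435), endothelial activation (13; 0.0287 and 0.241) and oligodendrocyte background (10; 0.0366 and 0.435) passed camera upwards, the last 3 not with the replicate block (adjusted p = 0.107, 0.0952 and 0.161). Of 29 alternative settings, 6, 9 and 15 ended these 3 calls. Unfolded protein response, identity and barrier, immediate early response, vascular background and glycolysis passed no test (0.0753 to 0.984), the last 2 with median and test or mean of opposite sign.

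Astrocyte-like cells made up a smaller share of the kept cells in transgenic mice, 6.99% ± 2.59 against 12.6% ± 2.69, as did perivascular macrophage-like cells, 1.80% ± 0.825 against 3.82% ± 1.02 (exact permutation adjusted p = 0.00451 for each, ranges overlapping). Neuron-like cells made up 2.36% ± 1.55 against 0.903% ± 0.630 (exact permutation adjusted p = 0.0222), dendritic cell-like cells 0.310% against 0.571% and committed oligodendrocyte precursor-like cells 0.365% against 0.175% (adjusted p = 0.0357 for each). Microglia-like cells, at 45.9% ± 10.5 and 37.3% ± 5.49, did not pass (0.112), nor did 11 further classes. With sign flips within replicate numbers 3 of the 5 passed, and the dendritic cell-like and committed oligodendrocyte precursor-like shares did not. Within Cell Ranger 5.0.0 libraries 6 classes passed.

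**Figure D4:**
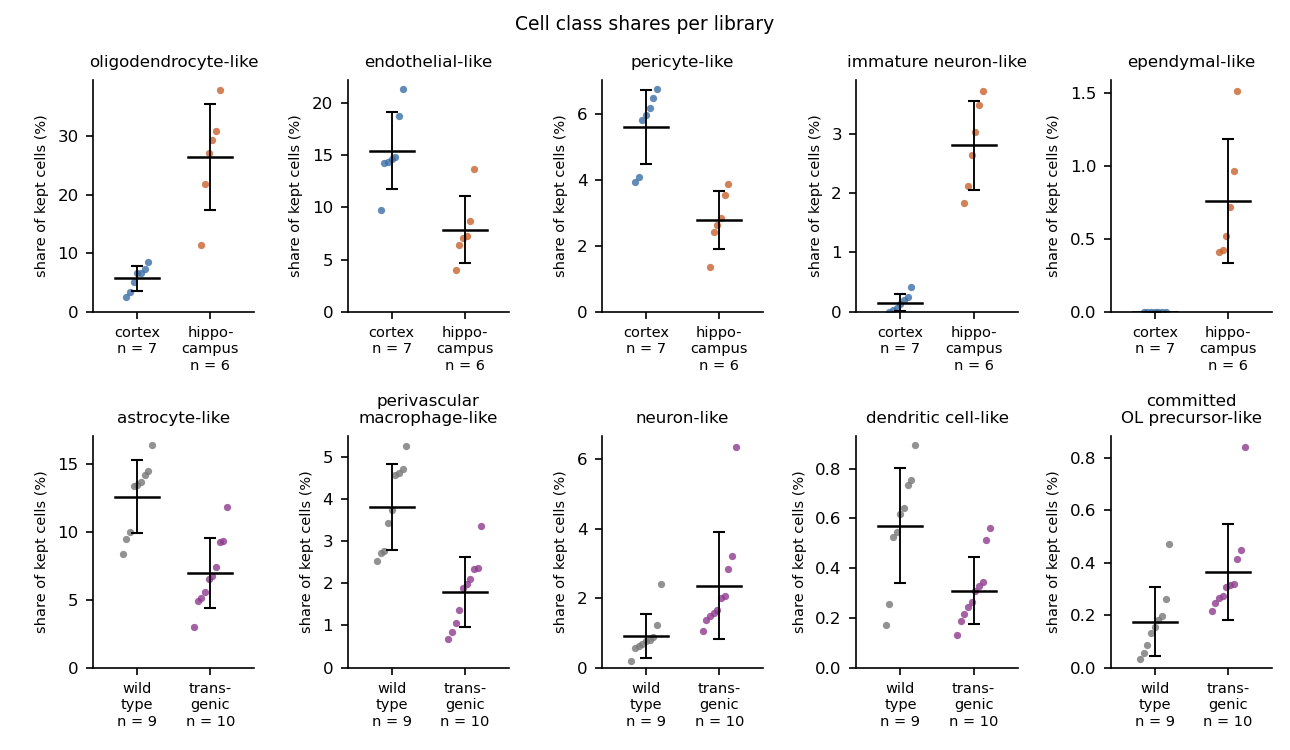
Share of kept cells in 5 classes per comparison, with points for libraries, bars for means and whiskers of 1 SD; cortex and hippocampus are in the upper row, wild-type and transgenic frontal cortex in the lower. Oligodendrocyte-like cells rise from 5.72% in cortex to 26.5% in hippocampus, and astrocyte-like cells stand at 12.6% in wild-type and 6.99% in transgenic frontal cortex.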

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

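Tests chosen only after the result was seen were those for free RNA as the source of genes more abundant in another class and of microglia background genes in astrocyte-like cells, that for doublets as the source of the latter's rise, and the comparisons in precursor-like cells.

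C4b and Serpina3n rose in 2 glial classes of the transgenic mice, and by more in oligodendrocyte-like than in astrocyte-like cells. On the scale of log2(CPM + 1), C4b rose by 2.24 in astrocyte-like and 3.76 in oligodendrocyte-like cells, a difference of -1.52 (exact permutation test, adjusted p = 0.000714). Serpina3n rose by 1.49 and 3.13, a difference of -1.64 (exact permutation adjusted p = 0.000119). Csf1 rose by 0.67 in astrocyte-like and 3.40 in microglia-like cells, a difference of -2.73, and Prnp by 0.84 in oligodendrocyte-like and 2.07 in precursor-like cells, a difference of -1.23 (exact permutation adjusted p = 6e-05 for each, 10 transgenic against 9 wild-type libraries).

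Between hippocampus and cortex 3 genes changed by different amounts in 2 classes of the same 6 and 6 libraries. Unc13c stood lower by -3.69 and -1.19, a difference of -2.51, and Hapln1 by -0.90 and -2.67, a difference of 1.77. Meox1 rose by 0.98 in endothelial-like and 2.32 in precursor-like cells, a difference of -1.34. Each has an exact permutation adjusted p = 0.002976. These 7 differences came from a family of 11 tests, of which 8 passed, and those of Eid1 (-0.26, exact permutation adjusted p = 0.229), Nr2e1 (0.44, adjusted p = 0.1) and Col16a1 (-0.55, adjusted p = 0.0754) did not pass.

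Among transgenic oligodendrocyte-like cells, the rise of C4b and Serpina3n was set against 2 technical explanations. Free RNA of other cells would bring both genes to endothelial-like and microglia-like cells of the same libraries, but C4b stood at 606.3 CPM in oligodendrocyte-like, 4.05 in endothelial-like and 2.41 in microglia-like cells, at most 0.668% of its level. Serpina3n stood there at 0.96% at most, though at 72.1% in precursor-like cells, where C4b stood at 9.92%. Another mix of clusters would leave a small change within them, but C4b rose by 4.31 in cluster 13 and 3.87 in cluster 15 against 3.83 in the class, and Serpina3n by 4.005 and 3.71 against 3.33, on the log2 scale. Both explanations are thus argued against for both genes, reads of C4b shared with the paralogue C4a were not tested, and a response of oligodendrocyte-like cells to the amyloid genotype stays open as a hypothesis.

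Microglia background genes were higher in transgenic astrocyte-like cells, by a median log2 change of 0.544. Doublets with microglia would put these UMIs in few cells, and the 5% of cells with the most of them held 35.3% (wild type 30.01%), a share of all UMIs that says little of the rise. Without the top 5% of each library the list's summed level rose by 0.54 on the log2 scale against 0.59 over all cells, which keeps 0.902 of the rise, but 0.645 to 1.00 with 1 library left out, between the bounds set. Free RNA of microglia would raise the list alike in other classes, and its median was 0.431 in oligodendrocyte-like and 0.472 in endothelial-like cells. Free RNA is thus a candidate explanation, and doublets and a change in astrocytes themselves stay open beside it.

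The rise of genes in hippocampal astrocyte-like cells fell into 2 parts. Of 237 risen genes that are not more than 5 times as abundant in another class, 166 were also tested in microglia-like cells, and their median log2 change was 0.852 in astrocyte-like cells but 0.107 in microglia-like and 0.0764 in endothelial-like cells (147 of the 237 tested) under the same contrast, which argues against free RNA for them as a set. With cells of both regions taken from 1000 to 3000 UMIs, where a different 166 of the 237 were tested and 71 were not, the median was 0.80 against 0.856 over all cells, 165 in the same direction, which argues against lower depth for those tested, although 36 kept their own call with fewer cells. For 537 risen genes that are more than 5 times as abundant elsewhere, the median was 1.57 in astrocyte-like and 0.469 in microglia-like cells, between the bounds set for free RNA, and 0.237 in endothelial-like cells (465 genes), under 1/4 of the astrocyte-like value, so that these classes give different answers and free RNA and a change in astrocytes cannot be told apart for these genes. Region stays open as the biological explanation, untested apart from dissection.

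Single libraries stood far from their group in 26 of 237 groups of values (10.97%), where chance gives about 1 in 20. Cortex replicate 0 accounts for 8 and hippocampus replicate 0 for 6, the pair counted with Cell Ranger 3.0.2 and among the shallow libraries. In astrocyte-like cells cortex replicate 0 had the lowest CPM of Tnc (6.30), Gabbr2 (48.3), Rgs7 (44.1) and Lrrc9 (1.05) and the highest of Agt (220.4), Six3 (1.05), Kcnj16 (138.6) and Gjb6 (1283). Hippocampus replicate 0 had the highest Lgr6 (19.6) and the lowest Hopx (214.5) there. In precursor-like cells it had the lowest Eid1 (75.3) and Unc13c (25.1) and the highest Nptx2 (37.6).

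Cortex replicate 5 had the lowest Unc13c in precursor-like cells (58.1 CPM). Neuron-like cells made up 6.36% of transgenic replicate 1 and 2.41% of wild-type replicate 1, the highest of each genotype, and committed oligodendrocyte precursor-like cells 0.843% of transgenic replicate 11. Wild-type replicate 7 had the highest share of microglia-like cells with a Cst7 UMI, 0.693%, and the highest Lgals3 (5.27 CPM), wild-type replicate 9 the highest Spp1 (26.1) and wild-type replicate 8 the lowest Il7r (26.7) and Lbr (24.8). Transgenic replicate 8 had the highest Col16a1 in astrocyte-like cells (220.1) and transgenic replicate 9 the lowest Cela1 in oligodendrocyte-like cells (8.52).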

How the results depend on the processing

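Leaving out low-UMI clusters or the 3 shallow libraries, and Cell Ranger versions as a term or singly, were chosen after seeing the data. The cause of a moved count was not tested unless its construction shows it.

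With RLE size factors, with doublets kept and, where not named here, with DESeq2, no low-count filter and stricter cells, counts of changed genes stayed within 1.5 times those reported. RLE and DESeq2 moved the median of all genes by under 0.1 on the log2 scale. DESeq2 called 95 genes between hippocampus and cortex in endothelial-like cells. Without the low-count filter 1017 genes passed between striatum and cortex and, between genotypes, 32 in astrocyte-like, 37 in oligodendrocyte-like, 3 in endothelial-like and 10 in precursor-like cells, where more genes are tested. At most 200 cells per library, which removes depth, gave for hippocampus against cortex 685 genes in astrocyte-like, 38 in microglia-like, 22 in endothelial-like and 498 in precursor-like cells, 206 for striatum against cortex, 149 against hippocampus, and 952 in transgenic microglia-like cells.

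Libraries with the larger feature table alone gave 2770, 390 and 120 genes in astrocyte-like, microglia-like and endothelial-like cells of hippocampus against cortex, 1690 for striatum against cortex and 967 against hippocampus. Without the 3 shallow libraries the counts were 3226, 508, 112, 2018 and 1168 in the same order. Leaving out low-UMI clusters gave 0 genes by edgeR in transgenic astrocyte-like cells (667 unadjusted), where 4 libraries dropped below the cell minimum. Cell Ranger 4.0.0 libraries alone gave 0 genes by edgeR in astrocyte-like (268 unadjusted), 259 in microglia-like, 6 in oligodendrocyte-like and 0 in endothelial-like cells (212 unadjusted), with 5 libraries left. Cell Ranger 5.0.0 libraries alone gave 1365 in microglia-like and 0 by edgeR in endothelial-like cells (287 unadjusted). Stricter cells (273 unadjusted), at most 200 cells (282 unadjusted) and no low-UMI clusters (256 unadjusted) also gave 0 in endothelial-like cells, against 1 by edgeR and 1 by DESeq2.

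The replicate block raised every count of changed genes. For hippocampus against cortex it gave 2730 in astrocyte-like (54.5% risen, against 62.6% without it), 458 in microglia-like (79.5% against 97.9%), 215 in endothelial-like (74.9% against 100%) and 1448 in precursor-like cells. Between genotypes it gave 4024 in microglia-like, 79 in oligodendrocyte-like (70.9% against 94.7%), 21 in endothelial-like (23.8% against 100%) and 42 in precursor-like cells (88.1% against 100%). Though 8 of 9 pairs passed 0.1 in transgenic astrocyte-like cells, not every pair did in 3 comparisons. There the block gave 1766 genes for striatum against cortex (59.6% risen against 74.5%; 2 pairs, correlations -0.0329 to 0.0404), 1015 against hippocampus (-0.149 to -0.102) and 107 in transgenic astrocyte-like cells (70.1% against 100%; 0.0645 to 0.506, 6 of 9 own numbers best). The own number was also best in 6 of 9 pairs in each other class compared between genotypes. Beyond these counts and the class shares below, the block ended no call of a named gene and no list call other than those given with it in the report.

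Leaving out 1 library gave 1064 to 2297 genes for hippocampus against cortex in astrocyte-like, 158 to 319 in microglia-like, 26 to 82 in endothelial-like and 429 to 1034 in precursor-like cells, the lowest without hippocampus replicate 6. It gave 123 to 1048 for striatum against cortex and 104 to 628 against hippocampus, where a lone striatal library is assumed to vary like the other regions. Between genotypes it gave 9 to 16, 1629 to 2604, 13 to 19, 0 to 2 and 5 to 7 in astrocyte-like, microglia-like, oligodendrocyte-like, endothelial-like and precursor-like cells.

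List calls not given in the report as ending in alternative settings ended in at most 5 of them. Direction reversed in few cases. Serpina3n in striatum went to -0.0565 without striatum replicate 5, and to 2.48 without striatum replicate 4. The oxidative phosphorylation list did so for hippocampal endothelial-like cells without hippocampus replicate 0 (camera adjusted p = 0.777, against 1.03e-06 without cortex replicate 0) and for transgenic astrocyte-like cells without low-UMI clusters (0.00353) and with Cell Ranger 4.0.0 alone (0.58). With that version alone the lists for cholesterol synthesis (0.0755) and unfolded protein response (0.785) in oligodendrocyte-like and lysosome (0.788) in endothelial-like cells reversed too. Named genes kept direction and call in 1778 of 1908 settings for hippocampus against cortex in astrocyte-like cells, 1189 of 1314 for striatum against cortex, 1061 of 1222 against hippocampus and 253 of 295 in transgenic astrocyte-like cells.

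Of class shares, 5 passed in each comparison. For hippocampus against cortex the count was 0 with sign flips within replicate numbers (exact permutation, smallest p 0.03125), 9 with Cell Ranger 6.0.0 alone and 9 without shallow libraries. Between genotypes it was 2 with stricter cells and 3 with sign flips. The shares of cells with a Gfap or Cst7 UMI kept direction and call in all settings run, with differences of 16.6 to 29.1 and 11.9 to 30.8 percentage points.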

Other observations

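The comparisons in oligodendrocyte precursor-like cells and their alternatives were chosen only after the data were seen, while the tests of links and of other splits were fixed before their results.

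Hippocampal oligodendrocyte precursor-like cells carried more RNA for the growth cone protein Gap43 and the homeobox genes Meox1 and Dbx2, and less for the matrix link protein Hapln1, the lipase Pnlip and the secretory granule protein Ptprn. Gap43 stood at 264 ± 35.9 CPM against 55.6 ± 10.3 in cortex (6 libraries each), a log2 change of 2.22 (SE 0.14, edgeR adjusted p = 1.75e-09). Hapln1 stood at 15.2 ± 7.54 against 92.94 ± 14.03 CPM (-2.48, SE 0.18, adjusted p = 7.77e-09), Meox1 rose by 2.24, Pnlip changed by -2.31 and Ptprn by -1.69. Of 12481 genes 520 rose and 349 fell, 290 and 229 of them not more than 5 times as abundant in another class. The replicate block gave 826 and 622. The count fell to 429 without hippocampus replicate 6 and 498 without cortex replicate 3. Oligodendrocyte background genes rose in 14 of 15 (14 risen and 1 fallen adjusted over the list alone, median 1.97, camera adjusted p = 8.38e-48, adjusted p = 0.000185 with an estimated correlation).

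In transgenic precursor-like cells 6 genes rose and 0 fell by edgeR (301 unadjusted), and DESeq2 called 8 and 0. The replicate block gave 37 and 5. Prnp rose by 2.08 (SE 0.11, edgeR adjusted p = 1.76e-13) and App by 0.90 (SE 0.13, adjusted p = 0.000644), each in 10 of 10 libraries above all 9, and Tmem108 by 0.61 (adjusted p = 0.0187). Antigen presentation genes rose in 2 of 11 (7 adjusted over the list alone, camera adjusted p = 4.21e-30, and 0.000276 with an estimated correlation). Microglia background genes moved up with them, by a median of 0.45 (0 of 14 past the threshold over all genes by edgeR, 2 adjusted over the list alone, camera adjusted p = 3.44e-08, adjusted p = 0.237 with an estimated correlation), as did interferon genes (0 of 9 and 2, 1.29e-09, and adjusted p = 0.0455). Whether reads of the transgenes, which carry App sequence under the Prnp promoter in this line, count towards these genes was not tested.

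Whether astrocyte-like and oligodendrocyte-like cells follow the microglial response was tested over the 10 transgenic libraries, as 3 correlations with the share of microglia-like cells with a Cst7 UMI. C4b of astrocyte-like cells had Pearson's r = 0.724 (permutation p = 0.0198, adjusted p = 0.0354; Spearman's rho 0.588, permutation p = 0.0804), 0.592 without the 2 libraries farthest from the median share and 0.734 in the 7 libraries of Cell Ranger 5.0.0. C4b of oligodendrocyte-like cells had r = 0.712 (permutation p = 0.0236, adjusted p = 0.0354; rho 0.649, permutation p = 0.0489), 0.462 without those 2 libraries and 0.744 within 5.0.0. Gfap of astrocyte-like cells had r = 0.256 (permutation p = 0.476; rho 0.309, permutation p = 0.385), 0.308 and 0.501, with a 95% interval from -0.446 to 0.763 that decides nothing. A shared driver such as plaque load may raise C4b and Cst7 together, but plaques were not measured, and 4.0.0 has too few libraries for its own value.

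Calls were counted in 100 splits of the libraries into groups of the same sizes, the real one included. For hippocampus against cortex 1 split, the real one, reached the count in astrocyte-like (1391, highest other 679), microglia-like (236, highest other 10), endothelial-like (58, highest other 10) and precursor-like cells (869, highest other 223). Between genotypes the same held in microglia-like (2114, highest other 908) and oligodendrocyte-like cells (19, highest other 3). In transgenic astrocyte-like cells 3 of 100 splits reached 12 genes (highest other 15), in endothelial-like cells 4 of 100 reached 1 gene (highest other 12) and in precursor-like cells 3 of 100 reached 6 (highest other 1661). These shares lie under the 5% set in advance. Any call reaches 1 gene, leaving chance open in endothelial-like cells. The split with 1661 genes kept replicate numbers 1, 7, 8 and 11 together, a sign of same-number structure.

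Among splits that part as many pairs of replicate numbers as the real one, the highest count other than the real one was 547 in astrocyte-like, 65 in microglia-like, 16 in endothelial-like (64 splits each) and 49 in precursor-like cells (32 splits) for hippocampus against cortex. The splits with 65 and 16 genes exchange replicate 0 alone, the pair of Cell Ranger 3.0.2. Between genotypes, over 100 such splits, it was 3 in astrocyte-like, 1281 in microglia-like, 10 in oligodendrocyte-like, 2 in endothelial-like (3 splits reached the real count of 1) and 5 in precursor-like cells, and those with 1281 and 10 exchange pair 11 alone.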
